A study of Mus musculus with 12 samples.

How the data were processed

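Mammary glands 3 to 5 of female FVB/N mice carrying MMTV-Wnt1 and MMTV-iFgfr1 were profiled at 4 weeks of age, 6 h after an intraperitoneal injection of vehicle or of AP20187. MMTV is a viral promoter that is active in the mammary epithelium. iFGFR1 is an inducible FGF receptor 1 fused to a drug-binding domain of the FKBP12 type, and AP20187 is the compound that brings 2 such domains together and so activates the receptor. Per the labels' protocols, the glands were cut up and digested in 1 mg/ml collagenase A for 2 h at 37 °C with 100 µg/ml cycloheximide, an inhibitor of translation elongation, and 0.5 µg/ml DNase was added before harvest. Epithelial cells were enriched by short spins, with no cell sort given in the labels. Each cell pellet gave an RNA library, made with a stranded poly(A) kit, and a ribosome footprint library, made from nuclease-protected fragments recovered on size-exclusion columns. The 12 libraries form 4 groups of 3: RNA and footprints, each with vehicle and with AP20187.

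The authors deposited raw counts of reads per gene symbol for the 12 libraries in a single table, with no normalization. Per the submitters' processing notes, bcl2fastq 1.8.3, cutadapt, STAR, Bowtie2 and HTSeq were used with genome build mm10, and the libraries were sequenced on a HiSeq 2500. The role and settings of each tool, the strand setting, the treatment of reads that map to several places and the region in which footprints were counted are not given in the sources used here. The table lists 7318 genes. How they were chosen is not given either, so the totals below are counts over the listed genes and not full sequencing depths, and many marker genes were not analysed here. Reads shared between near-identical copies can be split or lost by such counting, so values of histone, ribosomal protein and other multicopy genes, and of genes with an overlapping or antisense neighbour, are uncertain. Counts assigned to Wnt1, Fgfr1 and Fkbp1a can hold transgene reads beside those of the mouse's own genes.

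From these counts, CPM values, which are counts scaled to a common library size, were computed with TMM-scaled library sizes. Changes are therefore relative to the other genes, and a shift shared by most genes would not show. Genes passing the filterByExpr rule were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 2-sided p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. The RNA response was fitted on the 6 RNA libraries and the footprint response on the 6 footprint libraries, with treatment as the only term. The change in translational efficiency, which is footprints over RNA per gene, was tested as the interaction of assay and treatment in a single model over all 12 libraries. Every adjusted p of a gene comes from these fits unless another tool is named. Standard errors (SE) of log2 fold changes were derived from the F statistic, and SD is the spread of CPM over the 3 libraries of a group. The labels do not say whether a library came from 1 mouse or from a pool, so all p-values measure the spread between these samples, which may be partly technical.

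The 43 gene lists, the tests, the rule for named genes and all alternative settings but 4 were fixed before the data were examined. The lists cover signalling, translation, metabolism, the cell cycle, inflammation and markers of cell types. The 27 lists with at least 5 measured members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between members, adjusted over the lists of a comparison. Beside each list call stands its adjusted p with the correlation estimated from the data. No list passed that second test in any comparison, the lowest adjusted p being 0.44 in RNA, 0.113 in footprints and 0.859 in translational efficiency. The fry test, which asks whether members move together without reference to other genes, passed 12 lists in RNA, 13 in footprints and 0 in translational efficiency, where the lowest adjusted p was 0.797. "Adjusted over the list alone" gives the count of members that pass when the adjustment covers only that list.

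Named genes were Fgfr1 and Wnt1 as the genes of the transgenes, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 CPM and no overlap between the groups, and up to 4 measured members per list with the smallest p. Predicted genes, RIKEN clones and pseudogenes were left out, and some genes that met the rule are not reported here. Where no gene passed, the 5 smallest p-values were named. Fkbp1a, gene families defined by their symbols, 2 additional lists of hormone targets and 4 alternative settings were chosen after the values had been seen. The 14 families with at least 5 listed members were tested, and their leading members are in the closing section.

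The procedure was tested on simulated counts drawn with the means and library sizes of these libraries, with 200 genes changed. Of 100 genes changed by 2-fold, the RNA fit recovered 67, the footprint fit 15 and the translational efficiency fit 6. Of 100 genes changed by 4-fold, they recovered 100, 81 and 58. Among simulated calls 4.57% were false in RNA, 9.43% in footprints and 5.88% in translational efficiency. A list raised 2-fold was called by camera in 20 of 20 simulated RNA data sets, in which other lists were called 1 time in all. Simulated genes were drawn independently of each other. These data sets therefore do not test how often camera calls a list whose members vary together between libraries.

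Whether replicate numbers pair the vehicle and AP20187 libraries was checked by correlating, over genes, the deviations of same-numbered libraries from their group means. In footprints the correlations were 0.197, 0.269 and 0.38 for numbers 1, 2 and 3, all above the limit of 0.1 fixed beforehand. Differently numbered footprint libraries reached at most 0.0803. Deviations from a group mean cancel out within the group, so higher same-numbered values force lower differently numbered ones. The latter are therefore no independent evidence of pairing. In RNA the same-numbered libraries gave 0.186, -0.051 and -0.101, so a pairing did not show in the RNA values. Differently numbered RNA libraries reached 0.222 (vehicle 2 against AP20187 3), so values above the limit also arose without a shared number. The numbers may thus pair the preparations behind the footprint libraries, but this is not established, and the labels state no pairing. Each cell pellet gave both libraries, so such a pairing would hold for RNA too. A fit with the number as a block is given beside the footprint results. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom between 13.4 and 962.

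Alternatives tried were DESeq2 1.42.0 and limma voom with quality weights, 2 other scalings, no filter and a filter at 10 CPM, thinning to the smallest library, replicate blocks, an estimated correlation and fry for the lists, and leaving out each library in turn. Gene positions were taken from GENCODE release M21 for GRCm38, the assembly that mm10 names, in which 7144 of the 7318 symbols were matched. Figures were drawn with matplotlib 3.10.9.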

Results

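RNA and ribosome footprints were counted in unsorted mammary gland cells, enriched for epithelium by short spins, 6 h after vehicle or AP20187. The mice carried an active Wnt1 transgene and an inducible FGF receptor 1 in their mammary glands. AP20187 dimerizes and thereby activates the inducible receptor, so the comparisons ask what adding FGFR1 signalling to WNT signalling did to transcript levels, to ribosome occupancy and to their ratio, the translational efficiency. No group received AP20187 without the inducible receptor, so effects of the compound itself cannot be told apart from those of FGFR1 signalling. Each of the 4 groups held 3 libraries. Over the 7318 listed genes, the vehicle RNA libraries 1, 2 and 3 held 251874393, 124403219 and 99484140 counts and the AP20187 RNA libraries 237015762, 113384539 and 94513818. Footprint libraries were shallower, with 1867702, 1772969 and 4007613 counts with vehicle and 11018709, 3042199 and 3769368 with AP20187. A floor of 3 counts corresponded to between 0.0119 and 0.0317 CPM in RNA and, in the footprint libraries in the same order, to 1.61, 1.69, 0.749, 0.272, 0.986 and 0.796 CPM. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate libraries correlated at 0.960 to 0.989 in RNA and at 0.862 to 0.965 in footprints (Pearson r of log2 CPM across genes, which are not independent replicates). Fos, an immediate early transcription factor gene, took the largest share of footprints in every library, between 3.11% and 3.64% with vehicle and between 1.91% and 2.16% with AP20187.

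In RNA, the transgene-encoded genes and most measured luminal progenitor and endoplasmic reticulum chaperone genes rose with AP20187, and most fibroblast, endothelial, adipocyte and Schwann cell genes fell. Wnt1 rose from 28.9 ± 17.0 to 221 ± 80.5 CPM (mean ± SD, n = 3 per group), a log2 fold change of 2.93 ± 0.48 (SE, adjusted p = 0.00791). Fgfr1 rose from 325 ± 50.8 to 810 ± 267 CPM, by 1.32 ± 0.25 (adjusted p = 0.0106). Phlda1, a gene induced by FGF and ERK signalling, rose from 193 ± 30.2 to 962 ± 150.5 CPM, by 2.32 ± 0.19 (adjusted p = 0.00488). For each of these genes all 3 AP20187 libraries lay above all 3 vehicle libraries. Mouse Wnt1 lies on chromosome 15 at 98789857 to 98793837, Fgfr1 on chromosome 8 at 25513654 to 25575718 and Phlda1 on chromosome 10 at 111506286 to 111508645, all protein-coding genes on the plus strand of GRCm38.

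The largest rises past the threshold also held Klk10, a secreted serine protease, at 3.90 ± 0.51 (chromosome 7, 43781035 to 43785410), and the nucleoside transporter Slc28a3 at 3.60 ± 0.52 (chromosome 13, 58545399 to 58610877). They further held the matricellular protein gene Spp1 at 3.33 ± 0.41 and the Rac regulator Chn2 at 3.05 ± 0.37. Spp1 went from 492 ± 266 to 4954 ± 1204 CPM. The other genes among the 10 were Oas3 at 4.05, Serpinb9c at 3.45, Cmpk2 at 3.09, Gbp4 at 3.08 and Oas2 at 3.04, of which Oas3, Cmpk2, Gbp4 and Oas2 are interferon-stimulated genes. These 5 calls ended without RNA vehicle 3, with adjusted p-values of 0.0961, 0.0538, 0.112, 0.05 and 0.077 in that order. Without RNA vehicle 1, Oas3, Serpinb9c and Cmpk2 had adjusted p-values of 0.0801, 0.0515 and 0.0912, without RNA vehicle 2 Oas3 and Cmpk2 had 0.0567 and 0.0633, and without RNA AP20187 1 Oas3 had 0.0964. Among the largest falls, the keratin Krt4 (chromosome 15, 101918535 to 101924735) went from 18.2 ± 1.13 to 2.25 ± 1.32 CPM, a log2 change of -3.02 ± 0.42 (adjusted p = 0.00625). The lipid kinase gene Pik3c2g fell by 2.98, the fibrinogen chain Fgb by 2.97, the aldehyde oxidase Aox3 by 2.92, the alcohol dehydrogenase Adh1 by 2.91, Fhl1 by 2.91, the lectin Cd209b by 2.75, Aspa by 2.75 and haptoglobin, Hp, by 2.74. The falls of Adh1 and Cd209b were lost without RNA vehicle 2 (adjusted p 0.0585 and 0.0982), RNA vehicle 3 (0.0712 and 0.136) and RNA AP20187 1 (0.0795 and 0.128), and that of Cd209b also without RNA vehicle 1 (0.0661).

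**Figure D1:**
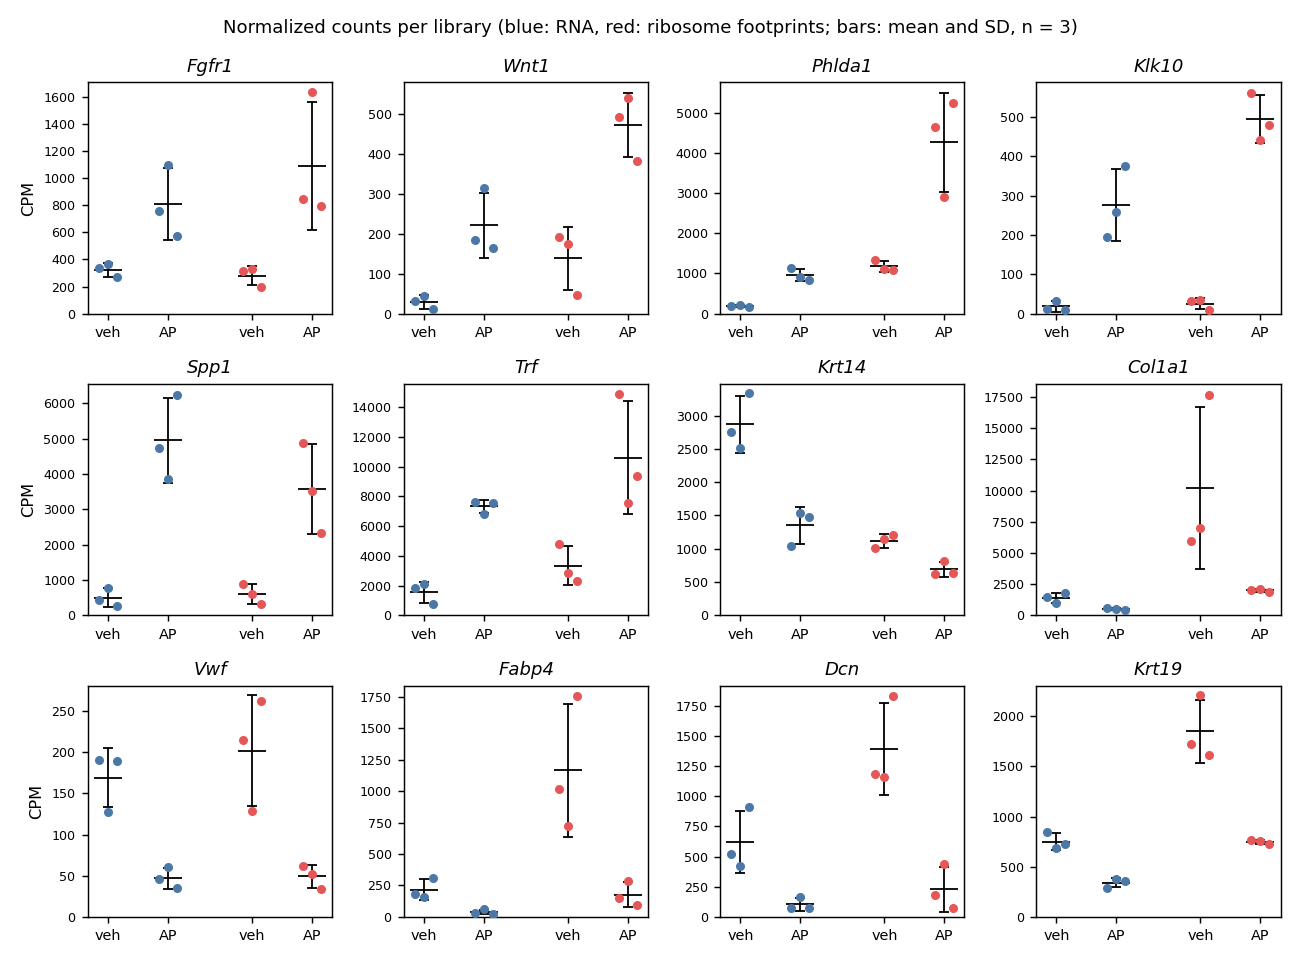
RNA and footprint levels (CPM, linear axes from 0) of 12 named genes in each vehicle and AP20187 library. Points are single libraries, bars are the mean and SD of the 3 libraries of a group, and Wnt1, Fgfr1, Phlda1, Klk10, Spp1 and Trf stand higher and Col1a1, Dcn, Vwf, Fabp4 and Krt19 lower with AP20187.

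Lists of luminal progenitor genes and luminal markers were higher in RNA, and those of fibroblast, endothelial, adipocyte and Schwann cell genes were lower. Of 10 measured luminal progenitor genes 8 rose and 2 did not pass (9 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 1.22 (camera adjusted p = 1.37e-04, adjusted p = 0.44 with an estimated correlation). Sox10, a transcription factor of progenitor cells, rose by 2.32 ± 0.34, the iron carriers Trf and Ltf by 2.25 ± 0.36 and 1.71 ± 0.25, and the lipopolysaccharide-binding protein gene Lbp by 1.02 ± 0.14. Of 11 luminal markers 8 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.94 (adjusted p = 0.0141, adjusted p = 0.44 with an estimated correlation). The junction genes Cldn7 and Epcam rose by 1.27 ± 0.12 and 1.03 ± 0.14, and the keratin Krt19 fell by 1.13 ± 0.16. Of 10 fibroblast genes 8 fell (10 adjusted over the list alone), with a median of -1.48 (adjusted p = 7.21e-06, adjusted p = 0.44 with an estimated correlation). The matrix genes Col1a1, Dcn, Lum and Col6a3 fell by 1.51, 2.59, 1.65 and 1.39. All 6 endothelial genes fell (6 adjusted over the list alone), with a median of -0.92 (adjusted p = 3.67e-04, adjusted p = 0.44 with an estimated correlation). Among them the clotting factor carrier Vwf fell by 1.84 and the adhesion receptor Pecam1 by 1.05. Of 10 adipocyte genes 6 fell (8 adjusted over the list alone), with a median of -1.87 (adjusted p = 0.00362, adjusted p = 0.44 with an estimated correlation). The lipid carrier Fabp4 fell by 2.47 and the fatty acid receptor Cd36 by 2.06. Of 8 Schwann cell genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -1.45 (adjusted p = 0.0141, adjusted p = 0.504 with an estimated correlation). The myelin gene Mag was among those that fell, and the gene that rose was Sox10, which is also in the progenitor list. In all 6 of these lists the medians of the 3 AP20187 libraries lay on one side of those of the 3 vehicle libraries. Without RNA vehicle 3 the counts that moved by over 1.5 times were 3 luminal markers that rose, 3 endothelial and 3 adipocyte genes that fell. Without RNA vehicle 1 and without RNA AP20187 1, 5 luminal markers rose in each case, and without RNA AP20187 1 also 3 adipocyte genes fell. In place of 2 luminal markers 1 fell without RNA vehicle 1, RNA vehicle 3, RNA AP20187 1 or RNA AP20187 3, and without RNA vehicle 2 single further genes passed, 1 progenitor gene that fell and 1 adipocyte gene that rose.

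Further lists called higher by camera were those of tRNA synthetases, endoplasmic reticulum chaperones, sterol synthesis, ribosome biogenesis, fatty acid synthesis, glycolysis and oxidative phosphorylation. As the stromal lists fell, the mix of cells may have changed. Whether that contributed to the rises of these lists, here or in footprints, was not tested. Of 20 cytosolic tRNA synthetases, the enzymes that charge tRNAs, 16 rose (18 adjusted over the list alone), with a median log2 fold change of 0.72 (adjusted p = 1.03e-07, adjusted p = 0.44 with an estimated correlation). Vars, Sars, Nars and Wars rose by 0.86, 0.85, 0.80 and 0.72. Of 18 endoplasmic reticulum chaperones 15 rose (15 adjusted over the list alone), with a median of 0.98 (adjusted p = 1.03e-07, adjusted p = 0.44 with an estimated correlation). Among them were Creld2 at 1.69, the disulfide isomerase Pdia4 at 1.56 and the chaperones Hyou1 at 1.29 and Dnajb11 at 0.92. Of 14 sterol synthesis genes 7 rose (9 adjusted over the list alone), with a median of 0.70 (adjusted p = 5.67e-04, adjusted p = 0.504 with an estimated correlation), including the enzymes Lss at 1.37, Dhcr7 at 1.30 and Pmvk at 0.89. Of 48 ribosome biogenesis genes 14 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.36 (adjusted p = 0.00137, adjusted p = 0.44 with an estimated correlation). Rrp1b rose by 0.94, and the gene that fell, Nop58, had adjusted p-values of 0.0765 without RNA vehicle 3 and 0.069 without RNA AP20187 1. In fatty acid synthesis 5 of 16 genes rose (6 adjusted over the list alone), with a median of 0.46 (adjusted p = 0.0141, adjusted p = 0.579 with an estimated correlation), and the malic enzyme gene Me1 rose by 1.06. In glycolysis 6 of 19 genes rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.37 (adjusted p = 0.0233, adjusted p = 0.504 with an estimated correlation). Both of these list calls were lost without RNA AP20187 2 (adjusted p = 0.0923 for each). In the nuclear-encoded oxidative phosphorylation list the median was 0.33 (adjusted p = 1.37e-04, adjusted p = 0.648 with an estimated correlation), yet 1 of 54 genes rose with edgeR (0 adjusted over the list alone, 13 at an unadjusted p under 0.05, 6 with DESeq2 and 21 with limma voom). Its vehicle 2 median of 0.30 lay above those of 2 AP20187 libraries, at 0.16 and 0.20. In the other 6 lists all 3 AP20187 medians lay above the 3 vehicle medians. Without RNA vehicle 3 the members that rose fell in number to 9 tRNA synthetases, 7 chaperones, 3 sterol genes, 1 ribosome biogenesis gene, 1 fatty acid gene and 0 glycolysis genes. Without RNA vehicle 1 they numbered 12, 7, 4, 1, 2 and 1, and without RNA AP20187 1 they numbered 12, 10, 6, 1, 3 and 3. Of the 2 glycolysis genes that fell, 0 passed without RNA vehicle 1 or RNA vehicle 3 and 1 without any single RNA AP20187 library. In the oxidative phosphorylation list 14 genes rose without RNA vehicle 2 and 0 without RNA vehicle 1, RNA vehicle 3, RNA AP20187 1 or RNA AP20187 3.

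Interferon-stimulated genes rose unevenly between libraries. Of 20 measured, 12 rose (16 adjusted over the list alone), with a median of 1.96 (adjusted p = 9.94e-05, adjusted p = 0.55 with an estimated correlation). Relative to the vehicle mean the list median was 2.92 in RNA AP20187 1, 0.54 in RNA AP20187 2 and 1.15 in RNA AP20187 3. Oas1a, an antiviral sensor gene, rose by 2.62 ± 0.54 (adjusted p = 0.0138). The number of members that rose was 1 without RNA vehicle 3, 3 without RNA vehicle 1 and 6 without RNA vehicle 2. In the list for epithelial-mesenchymal transition 7 of 10 genes fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.96 (adjusted p = 0.0204, adjusted p = 0.504 with an estimated correlation), and in each library the AP20187 median lay below the vehicle medians. The matrix gene Fn1 fell by 1.50, the integrin Itga5 by 1.09 and the transcription factor Zeb2 by 1.46, and Spp1 rose. Several of these genes are also expressed in stroma, and 4 fell without RNA vehicle 3 and 4 without RNA AP20187 1. In place of 2, 1 rose without each single RNA library other than RNA AP20187 3.

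Camera called none of the lists below in RNA, while fry called 1 of them, the ATF4 targets (adjusted p = 0.0292). Of 76 ribosomal protein genes 0 passed with edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma voom), with a median log2 fold change of 0.00. Among other genes whose transcripts carry terminal oligopyrimidine tracts 1 of 20 fell (1 adjusted over the list alone), namely the intermediate filament gene Vim by 1.21. Of 32 initiation factors and their regulators 5 rose (5 adjusted over the list alone), among them the cap-binding repressor Eif4ebp1 at 1.28 ± 0.23. Of 7 genes described as sensitive to eIF4E 3 rose (3, and 1 fell, adjusted over the list alone). Of 14 ATF4 target genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), led by the amino acid transporter Slc7a5 at 1.62 ± 0.21. Of 22 genes of the G1/S transition 3 rose and 1 fell (2 and 1 adjusted over the list alone). Of 20 G2/M genes 0 passed with edgeR (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 with DESeq2 and 8 with limma voom), although 8 rose without RNA vehicle 2 and 1 without RNA AP20187 2. In the insulin-like growth factor list 2 of 5 rose (2 adjusted over the list alone), including the receptor gene Igf2r at 0.94. Of 18 heat shock genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), the latter being Dnajb4 by 1.03, and of 5 macrophage genes 1 rose (2 adjusted over the list alone). Of 6 immediate early genes 0 passed with edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 1 with DESeq2 and 4 with limma voom), and Fos stood at 12619 CPM with vehicle and 9452 CPM with AP20187. Of 12 basal markers 5 fell and 1 rose (5 and 3 adjusted over the list alone), the myosin gene Myh11 by 1.68 and the keratin Krt14 by 1.08 among those that fell.

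Most of these small counts moved with single libraries. Genes that rose in the lists of initiation factors, eIF4E-sensitive genes, ATF4 targets, G1/S, the insulin-like growth factor axis, heat shock and macrophages numbered 1, 0, 1, 1, 1, 0 and 0 without RNA vehicle 3. They numbered 2, 0, 1, 0, 2, 0 and 0 without RNA vehicle 1, and 2, 1, 2, 2, 2, 2 and 0 without RNA AP20187 1. Without RNA vehicle 2, 5 G1/S genes and 3 macrophage genes rose and 1 eIF4E-sensitive gene fell. Without RNA AP20187 2, 4 heat shock genes, 2 eIF4E-sensitive genes and 2 ATF4 targets fell. Without RNA AP20187 3, 6 heat shock genes and 4 ATF4 targets rose, and 1 initiation factor and 2 G1/S genes fell. The ATF4 target that fell was not past the threshold without RNA vehicle 1, RNA vehicle 3, RNA AP20187 1 or RNA AP20187 3, and the G1/S gene that fell was not past it without the first 3 of these. Basal markers that fell numbered 2 without RNA vehicle 1, RNA vehicle 3 or RNA AP20187 1 and 3 without RNA vehicle 2, and those that rose numbered 0 without RNA vehicle 1 or RNA vehicle 3 and 2 without RNA vehicle 2 or RNA AP20187 1.

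Another 16 lists had fewer than 5 measured members, 2 of them none, and were not tested as lists. In the FGF and ERK feedback list 2 of 3 genes rose, Phlda1 and Sh3bp4, a gene of endocytic trafficking, the latter by 1.00 ± 0.16. Of 3 WNT targets, Procr, the protein C receptor gene, fell by 1.92 ± 0.25, and the transcription factor gene Sox9 rose by 0.95 ± 0.30. Of 4 genes for FGF receptors and ligands, Fgfr1 and Fgf2 rose and Fgf1 fell. The calls of Sox9 and Fgf2 were lost without 5 of the 6 RNA libraries, Sox9 being kept only without RNA AP20187 3 and Fgf2 only without RNA AP20187 2, with adjusted p-values of up to 0.162 and 0.146. The call of Fgf1 was lost without RNA vehicle 3 (adjusted p = 0.0521). Of 4 genes of the EGF family 0 passed with edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 with DESeq2 and 2 with limma voom), and 1 rose without RNA AP20187 2. Of 3 polyamine genes the spermidine synthase gene Srm rose by 1.63 ± 0.19, with 1 more passing without RNA vehicle 2. Of 4 inflammatory genes the lipocalin gene Lcn2 rose by 1.90 ± 0.34 and the adhesion receptor gene Icam1 fell by 0.99, a call lost without RNA vehicle 1, RNA vehicle 3, RNA AP20187 1 or RNA AP20187 2 (adjusted p up to 0.098). Of 2 matrix proteases the cathepsin gene Ctsb rose by 0.92.

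Of 4 hormone-sensing luminal genes, the fibrinogen chain Fgg fell by 1.53 and S100a6 by 1.48. Of 3 milk protein genes, Xdh, which is needed for milk fat secretion, rose by 1.57 ± 0.21 and the casein gene Csn3 by 2.53 ± 0.78. The call of Csn3 was lost without RNA vehicle 1, RNA vehicle 3, RNA AP20187 1 or RNA AP20187 3 (adjusted p up to 0.131). The milk gene Glycam1 stood at -3.07 ± 1.03 and did not pass (adjusted p = 0.0581), although all 3 AP20187 libraries lay below all 3 vehicle libraries, and it passed without RNA AP20187 2 or RNA AP20187 3. Des fell by 1.60 among 4 pericyte genes (2 fell without RNA AP20187 2) and Ttn, the giant muscle protein gene, by 2.09 among 4 skeletal muscle genes. Of 4 neutrophil genes S100a9 fell by 4.58 ± 0.98 from 4.04 ± 4.47 to 0.165 ± 0.0267 CPM, Ngp and Camp also fell, and S100a8 rose by 2.11 ± 0.65. S100a8 was lost without RNA vehicle 1, RNA vehicle 3, RNA AP20187 1 or RNA AP20187 3 (adjusted p up to 0.155), and Ngp without RNA vehicle 3 (0.0611). The call of Camp was lost without each single RNA library other than RNA vehicle 1 (adjusted p up to 0.188). The only measured erythroid gene, Bpgm, rose by 1.11, which was lost without RNA vehicle 1 (0.0559) and RNA vehicle 3 (0.0526), and the only measured T cell gene, Thy1, did not pass at -0.19 ± 0.17 (adjusted p = 0.441). Adjusted over the list alone, these counts were the same except that the cathepsin gene Ctsl, Glycam1 and the receptor gene Notch3 also fell.

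In RNA as a whole, edgeR called 1919 of 7314 tested genes, 906 higher and 1013 lower with AP20187, of which 725 changed by more than 2-fold. The groups did not overlap for 3291 of the tested genes, against 10% expected by chance, and the median SE of a log2 fold change was 0.176. The count was 717 without RNA vehicle 1, 538 without RNA vehicle 3, 782 without RNA AP20187 1 and 3721 with limma voom.

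Ribosome footprints, counted to ask which transcripts carried more or fewer ribosomes after FGFR1 activation, moved in the same directions for most named genes, with fewer of them past the threshold. Fgfr1 rose from 281 ± 72.5 to 1092 ± 472 CPM (mean ± SD, n = 3 per group), a log2 fold change of 1.96 ± 0.36 (SE, adjusted p = 0.0237), and Phlda1 from 1181 ± 132 to 4266 ± 1227 CPM, by 1.85 ± 0.30 (adjusted p = 0.0202). Wnt1 stood at 138 ± 79.7 CPM with vehicle and 471 ± 80.3 CPM with AP20187 and did not pass (1.78 ± 0.45, adjusted p = 0.0659), but it passed with the replicate number as a block (1.99, adjusted p = 7.68e-04). Klk10 rose from 25.4 ± 13.3 to 493 ± 61.0 CPM, by 4.31 ± 0.44, and S100a8, a calcium-binding protein of neutrophils and stressed epithelia, by 2.85 ± 0.30, each with an adjusted p of 0.00566. In all of these genes the 3 AP20187 libraries lay above the 3 vehicle libraries. The other largest rises were those of Oas3 at 5.19, the transcription factor gene Utf1 at 3.07, Slc28a3 at 3.03, the lipoprotein receptor gene Apobr at 3.00, the acyl-CoA synthetase Acsl4 at 2.99, the interferon-induced GTPase Igtp at 2.89, Chn2 at 2.88 and Spp1 at 2.57. Among the largest falls, the mast cell proteases Cpa3 and Mcpt4 fell by 4.53 and 3.77, the keratins Krt1 and Krt4 by 3.75 and 3.23, Hp and Fgb by 3.37 and 3.24, Sytl2 by 3.33 and the carbonic anhydrase Car3 by 3.23.

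Most of the lists that rose or fell in RNA were called in footprints too. Of 10 fibroblast genes 5 fell (10 adjusted over the list alone), with a median log2 fold change of -2.11 (camera adjusted p = 3.8e-09, adjusted p = 0.237 with an estimated correlation), and Col1a1, Col1a2, Gsn and Dcn fell by 2.36, 2.20, 2.62 and 2.61. Of 6 endothelial genes 2 fell (6 adjusted over the list alone), Vwf by 2.03 and the junction gene Esam by 1.41, with a list median of -1.34 (adjusted p = 6.58e-06, adjusted p = 0.237 with an estimated correlation). Of 6 Schwann cell genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -2.19 (adjusted p = 0.00117, adjusted p = 0.237 with an estimated correlation). The myelin scaffold gene Prx fell by 2.99, and Sox10 rose. Of 8 adipocyte genes 2 fell (5 fell and 1 rose adjusted over the list alone), Fabp4 by 2.72 and Car3, with a median of -1.89 (adjusted p = 0.00176, adjusted p = 0.237 with an estimated correlation). Of 12 basal markers 1 fell (5 adjusted over the list alone), the myosin kinase gene Mylk by 1.65, with a median of -0.82 (adjusted p = 0.00304, adjusted p = 0.372 with an estimated correlation). In the list for epithelial-mesenchymal transition 2 of 10 fell and 1 rose (6 and 1 adjusted over the list alone), and 8 of 10 fold changes were negative (adjusted p = 0.00453, adjusted p = 0.372 with an estimated correlation). The cadherin Cdh2 fell by 2.27, Fn1 by 1.70, and Spp1 rose. The immediate early list had a median of -0.39 (adjusted p = 0.0176, adjusted p = 0.237 with an estimated correlation), yet 0 of its 6 genes passed with edgeR (1 fell adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma voom). Fos stood at 34066 ± 4057 CPM with vehicle and 19828 ± 332 CPM with AP20187 (adjusted p = 0.125), and it passed with the replicate number as a block (-0.77, adjusted p = 0.028). The immediate early call was lost without footprint vehicle 3 (adjusted p = 0.0597) and footprint AP20187 2 (0.095). With the number as a block, 10 fibroblast, 6 endothelial, 4 Schwann cell, 4 adipocyte, 6 basal, 5 epithelial-mesenchymal and 2 immediate early genes fell, and 1 each rose in the Schwann, adipocyte and epithelial-mesenchymal lists.

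Among lists higher in footprints, 3 of 10 luminal progenitor genes rose (8 rose and 1 fell adjusted over the list alone), Ltf by 2.40 ± 0.46, Sox10 by 1.76 ± 0.33 and Trf by 1.67 ± 0.36, with a median of 0.98 (adjusted p = 5.42e-04, adjusted p = 0.237 with an estimated correlation). Of 11 luminal markers 1 fell (1 fell and 4 rose adjusted over the list alone), Krt19 by 1.30, while the list median was 0.75 (adjusted p = 0.0241, adjusted p = 0.356 with an estimated correlation). That list call was lost without footprint vehicle 2 (0.0717), footprint vehicle 3 (0.126) and footprint AP20187 1 (0.0937). Of 20 tRNA synthetases 1 rose (9 adjusted over the list alone), Aars by 1.14, with a median of 0.55 (adjusted p = 1e-06, adjusted p = 0.113 with an estimated correlation). Of 18 endoplasmic reticulum chaperones 2 rose (6 adjusted over the list alone), Sdf2l1 by 1.79 and Creld2 by 1.49, with a median of 0.76 (adjusted p = 6.58e-06, adjusted p = 0.245 with an estimated correlation). Of 20 interferon-stimulated genes 2 rose (12 adjusted over the list alone), Oas3 and the guanylate-binding gene Gbp2 by 2.00, with a median of 1.40 (adjusted p = 6.58e-06, adjusted p = 0.356 with an estimated correlation). Of 14 sterol synthesis genes 2 rose (3 adjusted over the list alone), Msmo1 by 1.57 and Lss by 1.50, with a median of 0.59 (adjusted p = 0.00237, adjusted p = 0.237 with an estimated correlation). Of 48 ribosome biogenesis genes 0 passed with edgeR (0 adjusted over the list alone, 8 higher and 1 lower at an unadjusted p under 0.05, 2 and 1 with DESeq2, 0 and 1 with limma voom), while the list median was 0.35 (adjusted p = 0.0019, adjusted p = 0.237 with an estimated correlation). Of 5 genes of the insulin-like growth factor axis 0 passed with edgeR (0 adjusted over the list alone, 3 higher at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma voom), while the list median was 0.72 (adjusted p = 0.0103, adjusted p = 0.237 with an estimated correlation). With the number as a block, 6 progenitor genes, 4 luminal markers, 9 tRNA synthetases, 9 chaperones, 11 interferon-stimulated, 3 sterol and 4 ribosome biogenesis genes rose, 1 luminal marker and 2 ribosome biogenesis genes fell, and 0 genes of the insulin-like growth factor axis passed. In all 15 called lists other than the basal markers, the medians of the 3 AP20187 footprint libraries lay on one side of those of the 3 vehicle libraries.

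**Figure D2:**
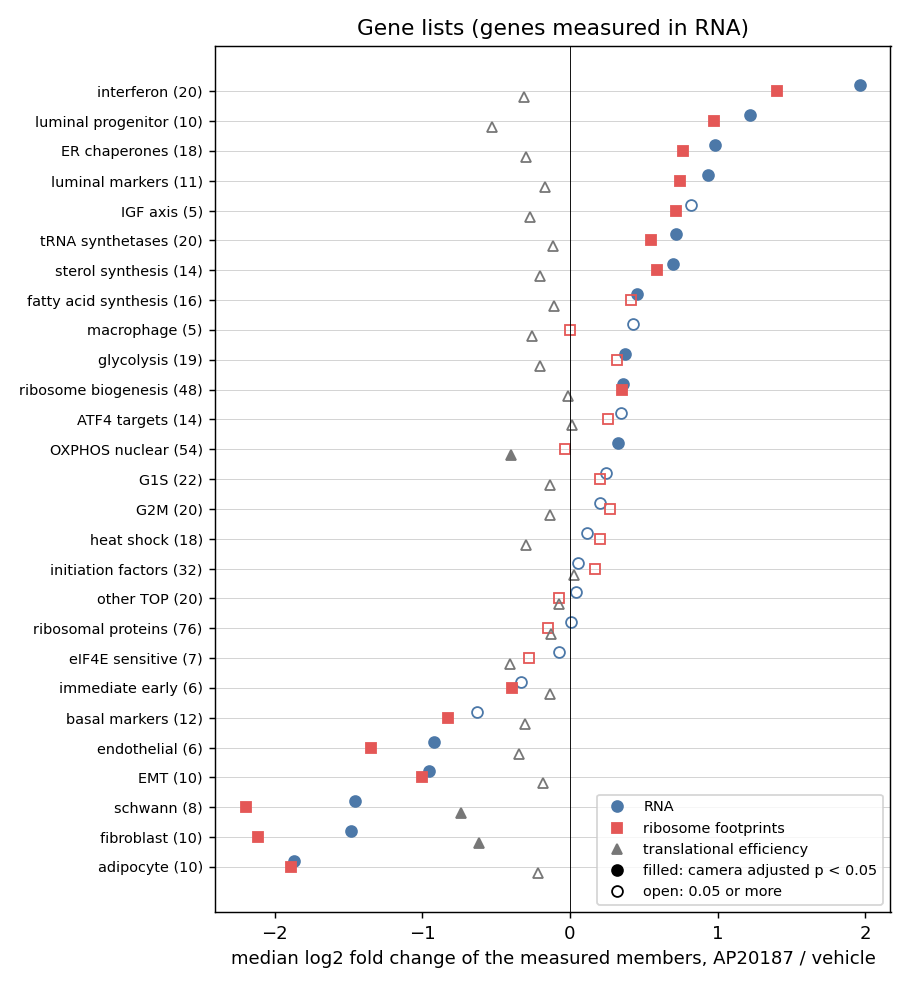
Median log2 fold change of each tested gene list in RNA (blue circles), in footprints (red squares) and in translational efficiency (grey triangles), with the number of genes measured in RNA in brackets. Filled symbols mark lists with a camera adjusted p under 0.05, which are 15 in RNA, 15 in footprints and 3 in translational efficiency.

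In the lists with no camera call in footprints few genes passed with edgeR, and fry called 2 of these lists, the initiation factors (adjusted p = 0.0447) and the ATF4 targets (0.0455). Of 58 ribosomal protein genes 0 passed with edgeR (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma voom), with a median of -0.15 (adjusted p = 0.159). Of 51 oxidative phosphorylation genes likewise 0 passed (0, 2, 0 and 0 by the same measures), with a median of -0.04. Of 32 initiation factors 0 passed with edgeR (0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 3 with DESeq2 and 2 with limma voom), with a median of 0.17 (adjusted p = 0.0883). Of 16 fatty acid synthesis genes 0 passed with edgeR (3 adjusted over the list alone, 5 at an unadjusted p under 0.05, 3 with DESeq2 and 3 with limma voom), and with the replicate number as a block this list was called at an adjusted p of 0.022. In the glycolysis, G1/S, G2/M, eIF4E-sensitive and macrophage lists 0 genes passed with edgeR (0 adjusted over the list alone), against 2, 1, 0, 0 and 0 at an unadjusted p under 0.05, 1, 1, 0, 0 and 0 with DESeq2, and 0, 1, 0, 0 and 0 with limma voom. Among the other genes with terminal oligopyrimidine tracts 0 passed with edgeR, and 1 did adjusted over the list alone, at an unadjusted p under 0.05, with DESeq2, with limma voom and without footprint AP20187 2. Slc7a5 rose by 1.29 in the ATF4 list (1 of 13, 1 adjusted over the list alone) and the heat shock gene Dnajb1 fell by 1.84 (1 of 18, 1 adjusted over the list alone). In the lists too small to test, Procr fell by 2.25, Icam1 by 1.63, Fgg by 2.02, S100a6 by 1.41 and Glycam1 by 3.05, and Xdh rose by 1.70. The EGF, polyamine, protease, pericyte, T cell, erythroid and skeletal muscle lists held 0 genes past the threshold with edgeR, against 0, 1, 1, 2, 0, 1 and 3 at an unadjusted p under 0.05, 0, 0, 1, 0, 0, 0 and 1 with DESeq2, and 1, 0, 0, 0, 0, 1 and 0 with limma voom. With the number as a block, 4 initiation factors, 5 fatty acid genes and 1 gene each of the heat shock, ATF4, G1/S and G2/M lists rose, 2 heat shock genes and 1 gene each of the glycolysis and other oligopyrimidine lists fell, and 0 ribosomal protein, oxidative phosphorylation, eIF4E-sensitive or macrophage genes passed. In the small lists of that fit 2 FGF feedback genes, 2 milk genes, the erythroid gene and 1 gene each of the FGF receptor, inflammatory and neutrophil lists rose. The genes that fell were 3 hormone-sensing genes and 1 gene each of the milk, protease, WNT target and inflammatory lists. Among EGF, polyamine, pericyte, T cell and skeletal muscle genes 0 passed. Adjusted over the list alone, 1 protease gene, the erythroid gene and 3 skeletal muscle genes passed, and 1 more gene each in the FGF feedback, FGF receptor, inflammatory, hormone-sensing and milk lists.

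In footprints as a whole, edgeR called 179 of 7041 tested genes, 66 higher and 113 lower with AP20187, all by more than 2-fold and without overlap between the groups, against 1160 at an unadjusted p under 0.05. The groups did not overlap for 23.2% of all tested genes, against 10% by chance, and the median SE of a log2 fold change was 0.337. With the replicate number as a block the count was 715, 353 higher and 362 lower, and it held all 179, while DESeq2 called 538 and limma voom 550. Without footprint vehicle 1 or footprint vehicle 2 it was 0, with 1116 and 1091 genes at an unadjusted p under 0.05. Without footprint vehicle 3 it was 3, namely Acsl4, Klk10 and S100a8, and without footprint AP20187 1 it was 2, namely Klk10 and S100a8, so every list count and named call of footprints above ended there except those of these genes. Without footprint AP20187 2, 8 fibroblast, 5 endothelial and 3 basal genes fell and 0 tRNA synthetases and luminal markers passed, and without footprint AP20187 3, 1 endothelial gene, 1 hormone-sensing gene and 0 basal markers fell, 1 luminal marker, 2 tRNA synthetases and 1 sterol gene rose. The calls of Krt1, Sytl2 and Icam1 were lost without any single footprint library, and Mcpt4, Apobr, S100a6, Mylk, Esam and Lss were also lost without footprint AP20187 3 and Fn1, Krt19 and Aars without footprint AP20187 2.

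Whether RNA and footprints changed together was compared over the 7041 genes tested in both. Of these, 168 changed in both, 60 higher in both and 108 lower in both, with 0 in opposite directions, against 8.42 and 14.9 expected of independent lists. Of 179 genes changed in footprints 178 had an RNA fold change of the same sign, and of 1825 changed in RNA 1693 (92.8%) had a footprint fold change of the same sign. The log2 fold changes correlated at a Pearson r of 0.775 and a Spearman rho of 0.673 across genes, which are not independent replicates. Among genes changed in RNA the slope of footprint on RNA fold change was 0.875. Each preparation gave both libraries, and the deviations of a preparation's RNA and footprint libraries from their group means correlated at 0.0531, 0.11 and 0.344 for vehicle 1 to 3 and at 0.45, 0.519 and 0.37 for AP20187 1 to 3. The fold changes of the assays are thus not independent of each other. With the replicate number as a block in both assays 462 genes changed in both, with DESeq2 487 and with limma voom 528. The count was 0 without footprint vehicle 1 or 2, 3 without footprint vehicle 3 and 2 without footprint AP20187 1.

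**Figure D3:**
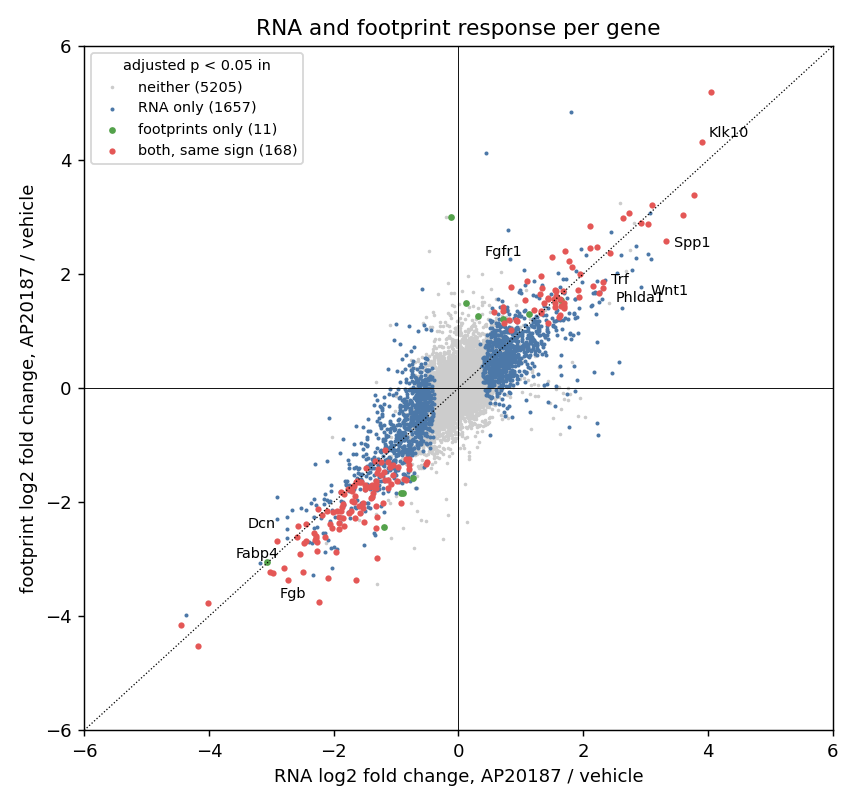
Log2 fold change with AP20187 in RNA (horizontal axis) and in footprints (vertical axis) for the 7041 genes tested in both, with a dotted line at equal change. Of the points, 168 changed in both, 1657 in RNA alone, 11 in footprints alone and 5205 in neither, and the genes changed in both lie in the lower left and upper right quadrants.

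Translational efficiency asked whether ribosome occupancy changed apart from transcript level, and 0 of 7315 genes passed with edgeR (350 at an unadjusted p under 0.05 where 365.75 are expected by chance, lowest adjusted p = 0.39). For the transgene-encoded genes the log2 change in efficiency was 0.59 ± 0.44 for Fgfr1 and -1.19 ± 0.70 for Wnt1 (SE, n = 3 per group and assay, adjusted p = 0.988 for both). The 5 genes with the smallest p failed the correction. Among them Apobr had 20 footprints over the 3 vehicle libraries and 423 over the 3 AP20187 libraries, with a change in efficiency of 3.12 ± 0.60, and Stx16, a gene of vesicle fusion, had 3 and 147, with 3.82 ± 0.77 (adjusted p = 0.39 for both). Ublcp1, Polr2l and AI413582 had 0 footprints with vehicle and 78, 47 and 77 with AP20187, which is at least 11.2-fold, 6.72-fold and 11.0-fold higher against a floor of 3 counts over the vehicle group. Without footprint vehicle 3 these bounds were 5.31-fold, 3.2-fold and 5.24-fold. With DESeq2 10 genes passed, 8 higher and 2 lower, and with separately fitted DESeq2 fold changes 1, Apobr, while limma voom called 0. Without footprint vehicle 2, 1 gene passed with edgeR, Stx16 (adjusted p = 0.0246). The groups did not overlap for 12.8% of genes, against 10% by chance, and the median SE was 0.392. As all values are relative to the other genes, a change in translation shared by most genes would not show here.

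Of the gene lists, 3 were lower in translational efficiency by camera, although 0 of their members passed with edgeR, DESeq2 or limma voom. The nuclear-encoded oxidative phosphorylation list had a median change of -0.40, with 53 of 54 members negative (camera adjusted p = 7.07e-06, adjusted p = 0.859 with an estimated correlation, 0 members adjusted over the list alone, 1 at an unadjusted p under 0.05). Cox5b, a subunit of cytochrome c oxidase, stood at -1.14 ± 0.37 (adjusted p = 0.893). The Schwann cell list had a median of -0.74 (adjusted p = 0.0195, adjusted p = 0.859 with an estimated correlation, 2 members adjusted over the list alone, 2 at an unadjusted p under 0.05), with Prx at -1.73 ± 0.46. The fibroblast list had a median of -0.62, with 10 of 10 members negative (adjusted p = 0.0439, adjusted p = 0.859 with an estimated correlation, 0 members adjusted over the list alone, 0 at an unadjusted p under 0.05). The Schwann call was lost without footprint AP20187 3 (0.288), footprint vehicle 3 (0.0702), RNA AP20187 2 (0.159) and RNA vehicle 2 (0.0544). The fibroblast call was lost without the first 3 of these (0.662, 0.357 and 0.159), RNA vehicle 2 (0.2), RNA vehicle 1 (0.0596) and RNA AP20187 1 (0.0527). With the replicate number as a block by assay, the fibroblast and Schwann calls ended (0.165 and 0.0563), and only the oxidative phosphorylation call remained. The oxidative phosphorylation call was kept without any single library (highest adjusted p = 0.0175).

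The lists of the translation machinery were not called by camera in translational efficiency. The median change was -0.13 for ribosomal proteins (adjusted p = 0.657), -0.07 for the other terminal oligopyrimidine genes, 0.03 for initiation factors, -0.01 for ribosome biogenesis, -0.12 for tRNA synthetases and -0.40 for the eIF4E-sensitive genes (adjusted p = 0.592). Over all genes the median was -0.08. In these lists 0 genes passed with edgeR, DESeq2 or limma voom and 0 adjusted over the list alone, while 8 ribosomal protein genes, 3 initiation factors and 2 ribosome biogenesis genes had an unadjusted p under 0.05. Ribosomal protein genes held few footprints, with a median level of 17.7 CPM against 620 CPM in RNA. Their values are therefore uncertain and do not show that their translation stayed the same. The cap-binding protein gene Eif4e stood at -1.17 ± 0.42 and its repressor Eif4ebp1 at -1.08 ± 0.40 (adjusted p = 0.985 and 0.988). Luminal progenitor genes had a median of -0.53 (adjusted p = 0.206), endoplasmic reticulum chaperones of -0.30 (0.111) and endothelial genes of -0.34 (0.167). In simulated counts at these depths 6 of 100 genes with a 2-fold change in efficiency were recovered, so changes of that size were mostly not detectable.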

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

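No test in this part was chosen after its own result was seen, and those on the oxidative phosphorylation genes were set once the change in that list was known but before they were run. In 3 gene lists the response to AP20187 differed between footprints and RNA by the interaction of assay and treatment, each lower in translational efficiency. The median difference was -0.40 for the nuclear-encoded oxidative phosphorylation genes (camera adjusted p = 7.07e-06), -0.62 for the fibroblast genes (adjusted p = 0.0439) and -0.74 for the Schwann cell genes (adjusted p = 0.0195). With an estimated correlation the adjusted p was 0.859 for all 3 lists, and the lowest adjusted p by fry was 0.797. Without footprint vehicle 3, footprint AP20187 3 or RNA AP20187 2 the fibroblast and Schwann calls ended (adjusted p between 0.0702 and 0.662), as they did without RNA vehicle 2 (0.2 and 0.0544). The fibroblast call also ended without RNA vehicle 1 (0.0596) and RNA AP20187 1 (0.0527). With the replicate number as a block by assay both calls ended too (0.165 and 0.0563), and only the oxidative phosphorylation call remained. Single samples far from the others were not searched for, since groups of 3 are too small for that test.

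The oxidative phosphorylation list had a median of 0.33 in RNA, where 1 of 54 members passed, and of -0.04 in footprints, and 53 of 54 members had a negative change in efficiency. A trend with coding length in the footprint libraries was tested, since the median coding length was 507 nt in the list against 1455 nt over all genes and changes in efficiency rose with length (Spearman rho 0.315 across 7132 genes, which are not independent replicates). With that trend removed from each library the list median went from -0.36 to -0.33 on the log2 CPM scale and camera still gave an adjusted p of 2.15e-04, which argues against length as the whole cause. A single library as the cause of the camera call was argued against too, since the highest adjusted p with 1 library left out was 0.0175 and the call ended without 0 of the 12 libraries. These fits kept the preset correlation, so they do not cover shifts that list members share within several libraries. In RNA the list median of vehicle 2, at 0.30, lay above those of AP20187 1 and 2, at 0.16 and 0.20. An effect of AP20187 on the translation of these transcripts and a difference between preparations in their RNA levels stay open, as neither was tested apart from the groups.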

How the results depend on the processing

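Of the tests in this part, 3 with RNA thinned to the depth of the footprint libraries and 1 with a minimum of 10 counts in every footprint library were chosen only after the data had been seen. No called gene or list named in the report reversed its direction under the alternatives run. The 1919 genes changed in RNA (906 higher, 1013 lower) became 3721 with limma voom (1870 higher, 1851 lower) and lay between 1281 and 2491 in the other 8 alternatives, among them 1643 at footprint depth (833 higher, 810 lower). Footprint depth alone therefore does not account for the smaller count of 179 in footprints. That count became 538 with DESeq2 and 550 with limma voom and lay between 160 and 198 with other scalings, filters and thinning. The count of 168 genes changed in both assays became 487 with DESeq2 and 528 with limma voom and lay between 145 and 186 in 6 other alternatives. For translational efficiency 10 genes passed with DESeq2 (416 at an unadjusted p under 0.05) and 1, Apobr, with separately fitted DESeq2 fold changes, while 10 further alternatives, limma voom among them, gave 0 (between 256 and 618 at an unadjusted p under 0.05). Among the 10 were Aak1, Akap9, Apobr, Brwd1, Rdh10, Stx16 and Ublcp1, all higher, and Hist1h2bf and Lama4, both lower. With an estimated correlation camera called 0 lists in RNA, 0 in footprints and 0 in translational efficiency, in place of 15, 15 and 3, and fry called 12, 13 and 0. The cause of these shifts was not tested. Of the named genes that were called, 68 of 120 in RNA and 0 of 51 in footprints kept the call under every alternative, leaving out each library included. In simulated counts at these depths 15 of 100 genes with a 2-fold change were recovered in footprints and 6 in translational efficiency, against 67 in RNA.

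With 1 library left out, genes changed in RNA numbered between 538 and 2214, with 717 without RNA vehicle 1, 538 without RNA vehicle 3 and 782 without RNA AP20187 1. More of them were higher than lower without RNA vehicle 2 (1043 higher, 997 lower) and RNA AP20187 3 (838 higher, 732 lower). Genes changed in footprints numbered between 0 and 186, with 0 without footprint vehicle 1 or 2 (1116 and 1091 at an unadjusted p under 0.05), 3 without footprint vehicle 3 and 2 without footprint AP20187 1. The same libraries set the count changed in both, which lay between 0 and 171. In translational efficiency the counts were between 0 and 1, the 1 being Stx16 without footprint vehicle 2 (adjusted p = 0.0246). Lists changed numbered between 14 and 19 in RNA and between 13 and 17 in footprints. In translational efficiency they numbered between 1 and 6, with 1 without RNA AP20187 2, footprint vehicle 3 or footprint AP20187 3, 6 without footprint AP20187 1 and 5 without footprint AP20187 2. The correlation of RNA and footprint fold changes lay between 0.685 and 0.765, at 0.712 without replicate 2 and 0.685 without replicate 3, against 0.775 with all libraries and 0.793 at 10 CPM or more. These fits hold fewer libraries, and no other cause was tested.

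The replicate number, for which a possible pairing showed in the footprint values but not in the RNA values, was added as a block. It raised the footprint count to 715 (353 higher, 362 lower, with all 179 kept), lowered the RNA count to 1281 (1211 of them shared with the 1919) and gave 462 genes changed in both, 150 of them shared with the 168. The larger side of the count in both turned from lower (60 higher, 108 lower) to higher (234 and 228). In translational efficiency 0 genes passed with a block by assay (540 at an unadjusted p under 0.05) or by preparation (412). Lists called in footprints became 16, with fatty acid synthesis added at an adjusted p of 0.022. A block by assay left 1 list in translational efficiency, oxidative phosphorylation, with adjusted p-values of 0.165 for fibroblast and 0.0563 for Schwann cell genes, and a block by preparation left all 3. The block changed no other list call in footprints or RNA, where it gave 15 lists again.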

Other observations

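In this part the gene families, Fkbp1a, the hormone target lists and the tests of stromal, luminal and luminal progenitor share and the expected number of zeros were chosen only after the data had been seen. Of 14 gene families defined by symbol, collagens, keratins, laminins, serpins and S100 genes were called lower in RNA with AP20187. Collagens fell for 11 of 15 genes, with a median log2 fold change of -1.13 (camera adjusted p = 2.98e-05), among them the fibrillar collagen gene Col1a2 from 1728 to 577 CPM, Col14a1 by 1.59 ± 0.27 (SE, n = 3 per group) and Col6a6 by 2.80 ± 0.51. Col9a1, a cartilage collagen gene, rose by 1.67 ± 0.49 but was lost without RNA vehicle 1 or any single RNA AP20187 library (adjusted p up to 0.111). Of 27 keratins 9 fell and 4 rose, with a median of -1.08 (adjusted p = 0.0122). Relative to the vehicle mean the keratin median was -0.12 in RNA AP20187 1, inside the vehicle range of -0.23 to 0.15, and -0.88 and -1.06 in RNA AP20187 2 and 3. Krt80, Krt23 and Krt7 fell by 2.11, 2.25 and 1.88, and Krt8 and Krt18 rose by 1.15 and 0.94. Keratins that rose numbered 1 without RNA vehicle 1 and 0 without RNA vehicle 3. Laminins, which build basement membranes, fell for 7 of 11 genes, with a median of -0.59 (adjusted p = 0.00656) and Lama2 lower by a log2 change of -1.67. Lama4 rose by 0.50, a call kept only when RNA AP20187 2 was the library left out (adjusted p otherwise up to 0.114). Laminins that fell numbered 1 without RNA vehicle 1, RNA vehicle 3 or RNA AP20187 1 and 4 without RNA AP20187 3. Among 12 serpins, protease inhibitor genes, 6 fell (3 without RNA vehicle 3) and Serpinb9c rose, with a median of -0.73 (adjusted p = 0.00316). Of 9 S100 genes 4 fell and S100a8 rose, with an adjusted p of 0.0243 that became 0.104 without RNA vehicle 2. Their median was -0.20 in RNA AP20187 3, above that of -0.25 in RNA vehicle 1. In footprints 8 collagens, 6 keratins and 5 laminins fell and Col9a1 rose, with medians of -1.76, -1.76 and -1.26 (adjusted p = 3.64e-08, 3.47e-06 and 8.75e-08). With the replicate number as a block 10 collagens, 7 keratins and 7 laminins fell and 1 collagen rose. The serpin Serpinb9 and the S100 genes S100a4 and S100a6 fell in footprints too, and S100a8 rose (adjusted p = 0.00117 for serpins and 0.0286 for S100 genes, the latter 0.125 without footprint vehicle 1 or footprint AP20187 3). With the block 4 serpins and 3 S100 genes fell. Without footprint AP20187 2, 3 keratins, 2 serpins and 1 S100 gene fell and 1 serpin rose. Without footprint AP20187 3, 3 collagens, 0 serpins and 0 S100 genes fell. Without footprint vehicle 1 or 2 no family member passed in footprints (1116 and 1091 genes of all kinds at an unadjusted p under 0.05), and without footprint vehicle 3 or footprint AP20187 1 only S100a8 did. With an estimated correlation no family passed in any comparison, with lowest adjusted p-values of 0.53 in RNA, 0.0784 in footprints and 0.587 in translational efficiency.

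Families called higher in RNA served interferon defence, protein turnover, mitochondrial translation and chromatin. Of 15 interferon-induced GTPases of the guanylate-binding kind 11 rose, with a median of 1.86 (adjusted p = 4.58e-04), led by Igtp at 2.93 ± 0.52. They numbered 2 without RNA vehicle 1, 4 without RNA vehicle 2, 1 without RNA vehicle 3 and 6 without RNA AP20187 1. Of 37 proteasome genes 8 rose, with a median of 0.39 (adjusted p = 2.98e-05). The groups overlapped, with library medians of 0.11 in RNA AP20187 2 and 0.25 in RNA vehicle 2. The immunoproteasome genes Psmb8 and Psmb9 rose by 1.13 ± 0.29 and 1.30 ± 0.35. Both were lost without single libraries (adjusted p up to 0.0998 and 0.115), and 0 proteasome genes passed without RNA vehicle 1, RNA vehicle 3 or RNA AP20187 1, 3 without RNA AP20187 3 and 16 without RNA AP20187 2. Of 71 mitochondrial ribosomal protein genes 12 rose, with a median of 0.38 (adjusted p = 4.53e-07), and Mrps2 rose by 0.90 ± 0.14. They numbered 1 without RNA vehicle 1 or RNA vehicle 3, 2 without RNA AP20187 1, 6 without RNA AP20187 3 and 25 without RNA vehicle 2. Of 86 solute carriers 19 rose and 7 fell (adjusted p = 0.041), with the nucleoside transporter Slc29a1 up by 1.62 ± 0.15. This call ended without RNA vehicle 2 (0.104) and RNA AP20187 2 (0.164). Those that rose numbered 9 without RNA vehicle 3, 10 without RNA vehicle 1 and 11 without RNA AP20187 1, and those that fell 3 without each of these, 4 without RNA AP20187 3 and 13 without RNA AP20187 2. In footprints 2 of 13 guanylate-binding genes rose, Gbp2 and Igtp (adjusted p = 3.66e-06, 8 with the replicate block and 6 without footprint AP20187 3), and 4 of 83 solute carriers (adjusted p = 0.0286, 10 with the block, with 1 that fell). The solute carrier call in footprints ended without footprint vehicle 2 (0.0741), footprint vehicle 3 (0.0523) and footprint AP20187 2 (0.0886). Of 37 proteasome genes 0 passed in footprints with edgeR (6 at an unadjusted p under 0.05, 2 with DESeq2, 2 with limma voom and 4 with the block), with a median of 0.23 and an adjusted p of 0.00401 that became 0.0613 without footprint vehicle 3. Of 70 mitochondrial ribosomal protein genes 0 passed there with edgeR (2 at an unadjusted p under 0.05, 0 with DESeq2, 0 with limma voom and 0 with the block), and this family was not called (0.147), although it was without footprint vehicle 1 (0.0275) and footprint AP20187 2 (0.0311). Class I histocompatibility, chaperonin, nucleoporin and importin genes were not called in RNA (adjusted p between 0.372 and 0.992).

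Histone genes stood apart between libraries and assays. In RNA 17 of 55 rose, with a median of 1.55 (adjusted p = 4.51e-08, but 0.53 with an estimated correlation), and the linker histone gene Hist1h1c went from 487 ± 135 to 1677 ± 889 CPM. Relative to the vehicle mean the family median was 1.67 in RNA AP20187 1, 0.06 in RNA AP20187 2 and 2.14 in RNA AP20187 3. Members that rose numbered 44 without RNA AP20187 2, 3 without RNA AP20187 3 or RNA vehicle 2 and 0 without RNA AP20187 1, RNA vehicle 1 or RNA vehicle 3. In footprints 0 of 55 passed with edgeR (0 at an unadjusted p under 0.05, 0 with DESeq2, 0 with limma voom and 0 with the replicate block), with a median of 0.01 that became -0.01 with upper-quartile scaling. Their translational efficiency had a median change of -1.45 (adjusted p = 1.48e-13, highest without any single library 1.76e-07, but 0.587 with an estimated correlation), while 0 members passed with edgeR (28 lower at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma voom). Most histone transcripts lack a poly(A) tail, and the RNA kit selects for such tails. The ratio of footprint to RNA CPM had a median of 306 over histone genes, 0.938 over all genes and 0.0309 over ribosomal protein genes, so efficiency values of these families are uncertain. Translational efficiency was also lower for mitochondrial ribosomal protein genes, by a median of -0.34 (adjusted p = 9.13e-05, highest without any single library 0.0309, but 0.916 with an estimated correlation), and for laminins and collagens, by -0.66 and -0.53 (adjusted p = 0.00144 and 0.0113). For importins it was higher, by 0.18 (adjusted p = 0.0339). The laminin and collagen calls ended without footprint vehicle 3 (0.088 and 0.446) and footprint AP20187 3 (0.0697 for both), that of collagens also without RNA vehicle 2 (0.0576) and RNA AP20187 2 (0.141). The importin call ended without RNA vehicle 1 (0.0638), footprint vehicle 1 (0.123), footprint vehicle 3 (0.13) and footprint AP20187 2 (0.196). In these 4 families 0 members passed with edgeR (1, 2, 0 and 1 at an unadjusted p under 0.05) or limma voom, and 1, the laminin gene Lama4, with DESeq2.

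Luminal genes rose in RNA while stromal genes fell, with list medians of 0.94 for luminal markers and -1.48 for fibroblast genes, of which the most abundant, Col1a2, went from 1728 to 577 CPM. Of the luminal markers 1, and of the fibroblast and endothelial genes 0, also stand in another list. A lower stromal share as the cause of the luminal rises would scale all luminal genes alike. Of 11 markers 4, Krt19, Ehf, Muc1 and Cldn7, lay more than 2 standard errors from the list median. Of these only Cldn7 rose, while Krt19, Muc1 and Ehf stood at -1.13, -0.77 and -0.14. A common scaling alone would not give the falls of Krt19 and Muc1. For the markers that rose it stays open, since Cldn7 was the only one that far from the median. A lower stromal share as the cause of the stromal falls stays open: 6 of 16 fibroblast and endothelial markers lay more than 2 standard errors from the median of their list, but 0 of them rose, and an uneven fall can also come from markers that remaining cells express. The short spins that enriched the epithelium removed an unknown share of other cells, and a change of expression within the stromal cells was not tested apart from it.

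The genes of the transgenes rose in RNA, Wnt1 by 2.93 ± 0.48, Fgfr1 by 1.32 ± 0.25 and Fkbp1a, which encodes the protein FKBP12, by 1.65 ± 0.27 from 107 ± 32.4 to 337 ± 92.0 CPM (mean ± SD), all kept without any single RNA library (adjusted p up to 0.0484). A larger share of all luminal cells alike was argued against as the sole cause of the Wnt1 rise. Wnt1 rose more than Cldn7, the luminal marker with the largest rise, by 1.66 ± 0.50. The luminal markers did not move alike, however, so they cannot exclude a larger share of some luminal cells. For Fgfr1 and Fkbp1a a larger luminal share stays open, as they exceeded Cldn7 by only 0.05 ± 0.28 and 0.38 ± 0.29. A larger luminal progenitor share stays open, as Wnt1 exceeded Sox10, the largest rise of that list, by 0.62 ± 0.59, within 2 standard errors. Glucocorticoid action on the MMTV promoter stays open as well: of 12 measured glucocorticoid targets 4 rose and 3 fell, with a median of -0.31 (95% bootstrap interval -0.52 to 0.61), and members that go both ways decide nothing. Action of FGFR1 signalling on that promoter was not tested, because reads of the transgenes and of the mouse's own genes share the same counts.

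The glucocorticoid targets had a median log2 fold change of -0.15 in footprints (95% bootstrap interval -0.95 to 0.38) and of -0.36 in translational efficiency (-0.41 to -0.20), where the median over all genes was -0.08. These intervals, like that in RNA, come from resampling the 12 genes and leave out the spread between libraries. In translational efficiency the unadjusted camera p was 0.0583, and 0.103 with an estimated correlation. In footprints these were 0.131 and 0.3, and 0 of 12 genes passed in either comparison. Of 2 measured targets of prolactin and STAT5, Bcl2l1, an inhibitor of apoptosis, rose by 0.75 in RNA and Akt1 did not pass. The call of Bcl2l1 ended without RNA vehicle 1, RNA vehicle 3 or RNA AP20187 1 (adjusted p up to 0.112). Fkbp1a stood at a log2 fold change of 1.04 ± 0.28 in footprints (adjusted p = 0.0812) and at -0.66 ± 0.38 in translational efficiency (adjusted p = 0.988).

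The 6 preparations can be split into 2 sets of 3 in 10 ways, too few for a share under 0.05. Splits with as many genes, the real one included, numbered 1 of 10 in RNA (1919 genes, highest other 0), 1 in footprints (179, highest other 0), 1 in both (168, highest other 0) and 10 in translational efficiency, where all splits gave 0. In footprints, where the numbers may pair the libraries, the 3 other splits that part all 3 possible pairs called 0 genes. All splits were fitted without the replicate number as a block.

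Zeros across a whole group were found in footprints but not in RNA. In all vehicle footprint libraries 37 genes were at 0, while 0 genes were at 0 in all AP20187 footprint libraries. Each of the 37 had at least 1 count in every AP20187 footprint library, even Hand2 with 1, 1 and 1. The vehicle libraries were shallower, with 7648284 counts in sum against 17830276, and 30 of the 37 genes had 30 or fewer counts with AP20187. At the vehicle depth 8.96 of the listed genes would be expected at 0 in all AP20187 libraries if counts were lost at random. How the listed genes were chosen is not given. A choice by detection in 1 group could shape both the 37 against 0 and this expected number, so no conclusion is drawn from them. The serpin gene Serpinb9c had 313 footprints with AP20187, 251 of them in library 1, which is at least 44.8-fold higher against a floor of 3 counts over the vehicle group. The interferon-induced GTPase gene Tgtp1 had 76, 63 of them in library 1, at least 10.9-fold higher. These bounds fell to 23.2-fold and 4.87-fold without footprint AP20187 1 and to 21.3-fold and 5.17-fold without footprint vehicle 3. Genes with at least 20 expected footprints but a count of 0 numbered 25, 0 and 19 in vehicle libraries 1, 2 and 3 and 2, 0 and 14 in the AP20187 libraries.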
